A study of Rattus norvegicus with 35 samples.

How the data were processed

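Messenger RNA was measured in the abdominal left mammary gland of 35 female Sprague-Dawley offspring, 5 animals in each of 7 groups, on 1-colour (Cy3) Agilent whole rat genome arrays. Per the labels' protocols, 150 ng of RNA was labelled for each array. Each array scan was deposited as a spot-level text output of Agilent Feature Extraction 9.5.3.1, and the authors also deposited 1 table of normalised values. Per the file headers, the processed signal of each spot is an intensity from which the local background had been subtracted, with spatial and multiplicative detrending and with values near the background replaced by small positive surrogates. Per the file headers, the mean spot signal and its local background are intensities without correction, and further deposited columns hold 0 or 1 flags (other) for saturation, outlying pixels and a signal well above background. The values in the authors' table are on a log2 scale. Column medians of that table ran from 6.55 to 6.58, so the authors had normalised between arrays, by a method that the processing notes leave unstated. Its ranks correlated at 0.959 to 0.998 (Spearman, across probes of 1 array) with the uncorrected mean signal and at 0.691 to 0.981 with the processed signal, and 194 of its values were missing.

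The processed signal was taken to log2 and centred on the 75th percentile of all probe spots of each array, and spots with outlier flags were then set to missing. Each of 263 probes is spotted 10 times and was averaged. The arrays carry 41012 probes besides 1639 control spots. Of these probes, 21252 were matched to the RefSeq gene table of the GRCr8 assembly (10735 by transcript accession, 1217 by gene ID, 1811 by symbol, 501 by an older symbol, 6988 by symbol without a suffix), and 19760 were not matched and kept the name in the array files. A probe was kept when its signal was well above background on at least 4 of the 5 arrays of at least 1 group, and 1 probe (the brightest) stood for each gene, which left 16157 genes, 9400 of them named through RefSeq. Genes could miss a value on at most 5 arrays. The main fit left such values missing. For list tests, list means, random blocks, array weights, the variance trend and regroupings of arrays, they were filled with the mean of their group. Expression is given as log2 relative to the array's 75th percentile, and differences as log2 fold changes with the standard error of the fit.

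Group means were fitted to all 35 arrays with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with empirical Bayes moderated variances. The contrasts were each bisphenol A (BPA) dose against control, both doses against each other and their mean against control, genistein or indole-3-carbinol (I3C) added to each BPA dose and averaged over both, the 4 combined groups against control, and the difference of each dietary effect between BPA doses. An F test asked for any difference among the 7 groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 16157 genes of 1 contrast. The labels hold no group with genistein alone or I3C alone, so each diet is compared at a fixed BPA dose.

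There were 31 gene lists, 18 of pathways and 13 of cell types that a whole fat pad could hold. Of these, 28 had at least 5 measured members and were tested in 6 comparisons, 168 pairs in all, with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 168 pairs. The list shift is the mean log2 fold change of the members minus that of all genes. Its standard error comes from a fit of the per-array list means. Each pair was also tested with a correlation estimated from the data, with fry, and by an exact two-sided permutation of the per-array list means of 5 against 5 arrays, whose smallest possible p is 0.00794. The exact permutation p was under 0.05 for 11 pairs and for 0 after adjustment. With this smallest p, no pair could pass adjustment over 168 pairs unless many others were as small. Members were also counted when adjusted over the list alone.

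Genes were named by rule: per single comparison the passing genes with the largest fold change, up to 10 per direction. A direction with fewer was filled up to 5 with the genes of smallest unadjusted p and an absolute log2 fold change of at least 0.58, described as not passing. Esr1, Esr2, Pgr, Gper1, Ahr, Cyp1a1, Cyp1b1 and Csn2 were always looked up, as were up to 4 members with the smallest p of each called list. The contrasts, the test, the lists, the naming rule and all but the last 4 alternatives given below were fixed before the data were examined.

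The file headers place the arrays on 10 slides scanned on 5 days. Slide explained 61.4% of the variance of the normalised values, scan day 39.4%, replicate number 37.6% and group 16.4%, each taken alone. These shares are not corrected for the number of levels, and more levels give a larger share by chance. The share of group is no more than random labels for 7 groups would give on average. The share of probes well above background was 31.9% to 96.4% per array (median 45.4%), and the number of arrays limits the precision of every value. Within-slide differences are given for many of the lists where groups share a slide. Slide 6 held 1 BPA25 array only.

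Same-number arrays correlated above 0.1 in all 5 pairs (after removing group means) for BPA25 against control (0.124 to 0.896) and for genistein added to BPA250 (0.233 to 0.662). A fit with the replicate number as a replicate block called 0 genes in each, as did the fit without it. Same-number arrays were often run on 1 slide, but not always (BPA25 and control replicates 3 were on slides 6 and 7). In both comparisons they also shared a scan day, except BPA25 and control replicates 3, so these are largely pairs of scan day. What these correlations come from was not tested. The labels give replicate numbers and state no pairing. The same-number array was the best-correlated one of the compared group for 2 of 5 BPA25 arrays and 3 of 5 BPA250+genistein arrays. For these 2 comparisons an exact sign-flip test of list means over the 5 pairs was added after seeing the data.

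Alternatives in processing were normexp background correction of the mean signal (offset 50), quantile normalisation, median scaling and the authors' table. Others were no filter or a stricter filter, every probe tested separately and outlier spots kept. Blocks were slide as a fixed or random block, scan day as a fixed block and replicate number as a replicate block. A number in the file names was a random block, taken within each group (23 combinations of group and number, 24 arrays sharing one). List means of muscle, B cell and luminal markers were covariates in a further fit. The rest were array weights, a variance trend with robust fitting, only the compared groups in the fit, and each array left out in turn. Further ones were chosen after seeing the data: leaving out the 4 arrays of slide 3, a 75th percentile taken over probes detected on all arrays, quantile normalisation with slide as a fixed block, and slide as a random block without slide 3. Scaling moved the median of all genes by more than 0.1: for I3C added to BPA250 it was 0.24 with the 75th percentile, 0.58 with median scaling and -0.16 with the percentile of detected probes. For I3C added to BPA25 it was 0.13, 0.25 and -0.02, and for genistein added to BPA25 it was 0.03, -0.25 and 0.06. List shifts are therefore stated relative to all genes.

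The procedure was tested on simulated data that kept each gene's mean and residual spread over the 35 arrays, with independent genes and no slide differences, and with set changes in the BPA25 arrays (15408 genes, 5 runs, 250 changed genes at each size). It recovered 16.8% of genes changed 2-fold, 76% at 4-fold, 96% at 8-fold and 99.6% at 16-fold, with 32 false calls over the 5 runs. No other series was combined with these arrays. What the number shared between file names stands for is not stated. Were it a litter, each group would hold 3 or 4 litters, and 5 arrays per group would overstate the independent animals behind each test. The correlation within numbers of a group was 0.029, and equal numbers in different groups were treated as different. Probe positions in the array files refer to the rn3 assembly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.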

Results

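Transcripts of the abdominal left mammary gland were measured in 35 female rat offspring at postnatal day 21, whose dams had been dosed from gestational day 10 to 21. The control group, BPA at 25 µg/kg/day (BPA25) and BPA at 250 µg/kg/day (BPA250) held 5 animals each. At both BPA doses 5 more animals came from dams fed genistein, a soy isoflavone (250 mg/kg chow, about 5.5 mg/kg/day), and 5 from dams fed I3C, a compound of cruciferous vegetables (2000 mg/kg chow, about 45.0 mg/kg/day). BPA, bisphenol A, is a plastics monomer that binds oestrogen receptors. The title of the series puts prenatal BPA and both diets in relation to early mammary development and later carcinogenesis. The comparisons therefore ask what each BPA dose left in the gland at weaning and whether either diet altered it. Fold changes below are log2 values from limma with their standard errors, from 5 arrays per group unless stated, and group values are means with SD.

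On the 4 arrays of slide 3, which were control, BPA25, BPA250 and BPA25+genistein replicates numbered 2, 93.4% to 96.4% of probes were well above background. On slides 4 and 5 it was 65.2% to 72.2% of probes, and on the other slides 31.9% to 49.8%. The 75th percentile signal was 375 to 876 on slide 3 and 30.4 to 338 on the others, while negative control spots were no brighter there (up to 85.2 on slide 3, 113 on slides 4 and 5 and 165 elsewhere).

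**Figure D1:**
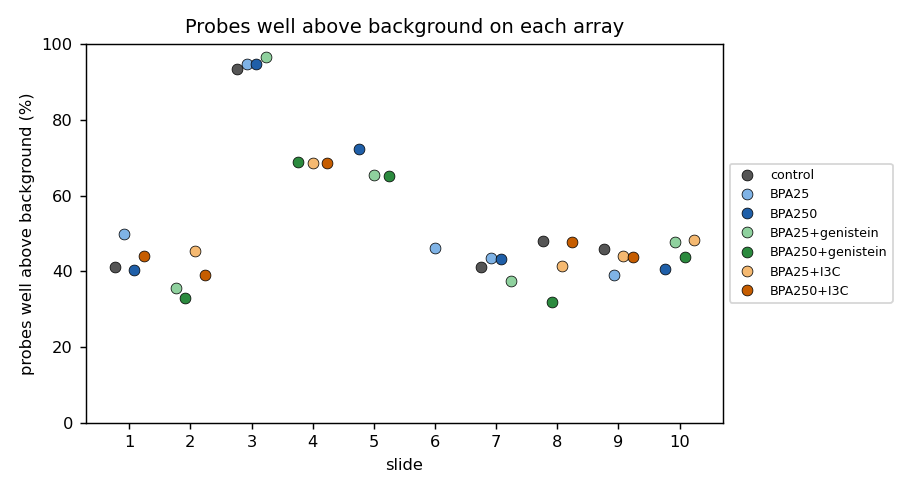
Percent of probes well above background on each of the 35 arrays (y axis) by slide (x axis), with 1 point per array coloured by group. The 4 arrays of slide 3 lie between 93.4% and 96.4%, and the arrays outside slides 3, 4 and 5 lie between 31.9% and 49.8%.

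The receptors through which these compounds are known to act gave little signal. Esr1 (oestrogen receptor alpha) was above background on 10 of 35 arrays, 6 of them outside slide 3. Pgr (progesterone receptor) stood at 10 and 6 arrays, Gper1 (membrane oestrogen receptor) at 8 and 4, Esr2 (oestrogen receptor beta) at 4 and 0, Ahr (aryl hydrocarbon receptor) at 6 and 2, and Cyp1a1 (its classical target) at 13 and 9. None of these 6 genes was kept by the filter on dim probes, so no difference in them was detectable at this signal. Cyp1b1, a further Ahr target, was above background on 35 arrays and Csn2, the gene of beta casein, on 34. Neither passed in any of the 6 single comparisons: Cyp1b1 log2 fold changes ran from -0.29 ± 0.45 (genistein added to BPA250) to 0.35 ± 0.45 (BPA250 against control), and Csn2 from -0.01 ± 0.49 (BPA250 against control) to 0.72 ± 0.49 (genistein added to BPA250). The sign of the smaller of these differed between scalings. The other Cyp1b1 probe stood at 0.55 with I3C and 0.44 with genistein added to BPA25.

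After BPA25 alone, transcripts of fat and sterol synthesis were higher than in control. The fatty acid and triglyceride synthesis list rose by 0.72 ± 0.38 relative to all genes, with 14 of 17 measured members higher, and the cholesterol synthesis list by 0.45 ± 0.25, with 15 of 16 higher. Examples are Acss2 (acetyl-CoA synthesis from acetate, 1.07 ± 0.36), Pnpla3 (a lipid droplet acyltransferase and lipase, 1.58 ± 0.65), Me1 (NADPH-producing malic enzyme, 1.42 ± 0.67), Fdps (farnesyl diphosphate synthase, 0.94 ± 0.42) and Cyp51 (lanosterol demethylase, 0.67 ± 0.32). None of these genes passed alone. Camera adjusted p values were 2.7e-07 and 8.6e-06, and with an estimated correlation the adjusted p values were 0.558 and 0.563. The exact permutation p of the list means of 5 against 5 arrays was 0.127 and 0.143. In the 5 pairs of same-number arrays both lists were higher with BPA25 in 5 of 5, with an exact sign-flip permutation p of 0.0625 each, the smallest that 5 pairs can give (adjusted 0.768). On the 4 slides that held both groups the BPA25 array had the higher list mean on all 4, by 0.06 to 1.41 for fatty acid synthesis and by 0.05 to 1.01 for cholesterol synthesis.

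Schwann cell markers also rose with BPA25 (shift 0.51 ± 0.27, 5 of 8 higher, camera adjusted p = 0.0064, adjusted p = 0.471 with an estimated correlation), led by Mbp (1.30 ± 0.55) and Prx (1.01 ± 0.48), both myelin genes. Endothelial markers (0.25 ± 0.16, 11 of 13 higher, adjusted p = 0.0216, adjusted p = 0.471 with an estimated correlation) and oxidative phosphorylation (0.22 ± 0.32, 17 of 19 higher, adjusted p = 0.0421, adjusted p = 0.983 with an estimated correlation) passed as well, with Eng (0.77 ± 0.45) and Atp5f1b (0.65 ± 0.49) as the first members. The endothelial adjusted p was 0.113 with slide as a fixed block. The endothelial call ended without control replicate 3 or 4 or BPA25 replicate 1 or 2 (shifts 0.17 to 0.24), the Schwann call without control replicate 4 or BPA25 replicate 1, 2 or 5 (0.32 to 0.52), and the oxidative phosphorylation call without control replicate 1 or 2 or BPA25 replicate 1, 3, 4 or 5 (0.009 to 0.21), while it was 0.34 without control replicate 4 and 0.47 without BPA25 replicate 2. Oxidative phosphorylation turned to -0.09 with normexp correction. The 5 lists had 0 members passing when adjusted over the list alone.

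Gene by gene, limma called 0 of 16157 genes between BPA25 and control, with 324 at an unadjusted p under 0.05 where chance alone gives 808 on average. Genes vary together, so counts by chance spread widely about 808, here and below. The smallest unadjusted p among genes with higher values belonged to Pisd (mitochondrial phosphatidylserine decarboxylase, 0.91 ± 0.26), Ap3m1 (vesicle adaptor subunit, 0.93 ± 0.31, its other probe 0.54), Pakap (1.00 ± 0.33), Acss2 and Uros (haem synthesis, 0.91 ± 0.32). Among lower values it belonged to Cdkl3 (-0.76 ± 0.25), Cdk12 (transcription kinase, -0.99 ± 0.33), Zbtb16 (a glucocorticoid-induced transcription factor, -1.88 ± 0.65), Cdh11 (mesenchymal cadherin, -0.90 ± 0.32) and Per1 (circadian clock, -1.04 ± 0.38). All 10 had an adjusted p of 1 in limma. Pisd, Pakap, Acss2, Uros, Cdkl3, Cdk12, Zbtb16 and Per1 kept their direction on 4 of 4 shared slides.

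After BPA250 alone, skeletal muscle transcripts fell by 2.42 ± 1.20 on the log2 scale relative to all genes, with 23 of 23 measured members lower than in control. Tnni1 (slow muscle troponin I) stood at -2.84 ± 0.83, Mb (myoglobin) at -1.73 ± 0.67, Atp2a1 (sarcoplasmic calcium pump) at -2.94 ± 1.20 and Myh7 (slow myosin) at -2.97 ± 1.22. Camera gave an adjusted p of 5.1e-42, and the call held with an estimated correlation (adjusted p = 0.0441). The list mean was -0.14 (SD 1.83) against 2.29 (SD 0.96) in control, with an exact permutation p of 0.0159 (5 against 5 arrays, adjusted 0.727). It was lower on 3 of 3 shared slides, by 0.57 to 5.41 (-5.41 to -0.57), and the shift with slide as a fixed block was -1.95 ± 1.16. Of the 23 members 1, Tnni1, passed when adjusted over the list alone and 0 over all genes.

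**Figure D2:**
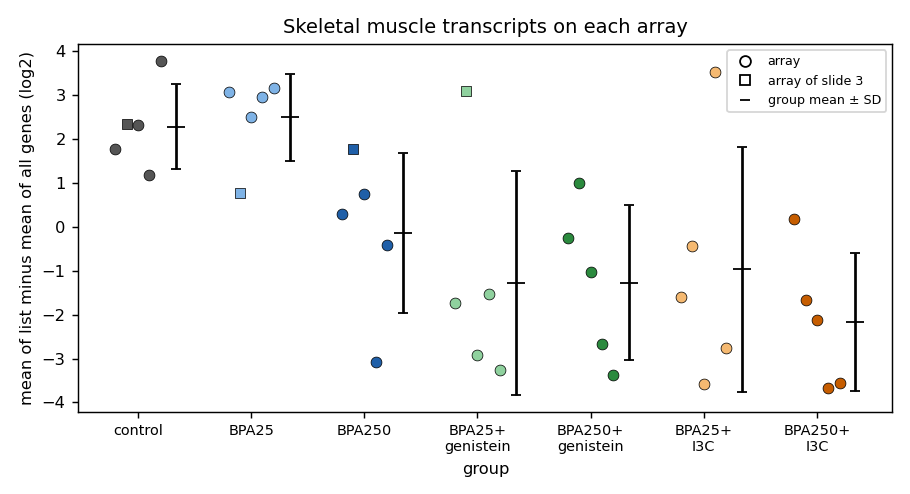
Mean of the skeletal muscle list minus the mean of all genes (log2, y axis) on each array by group (x axis), with squares for the arrays of slide 3 and a bar for the group mean and SD (n = 5). Control arrays lie between 1.19 and 3.79, and the BPA25+genistein array on slide 3 (3.1) lies far above the other arrays of its group (-3.27 to -1.54).

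Interferon-stimulated genes fell by 0.37 ± 0.18 with BPA250, with 10 of 11 lower (camera adjusted p = 9.0e-06, adjusted p = 0.322 with an estimated correlation). Oas1a (-0.76 ± 0.27) and Isg15 (-1.04 ± 0.40), both antiviral effectors, led the list. Without control replicate 4 the shift was -0.24. T cell markers (-0.64 ± 0.79, 7 of 7 lower, adjusted p = 0.0109, adjusted p = 0.825 with an estimated correlation) included Cd3e at -1.21 ± 0.86. Erythroid markers (-0.42 ± 0.41, 6 of 6 lower, adjusted p = 0.0264, adjusted p = 0.789 with an estimated correlation) included Hbb at -0.57 ± 0.62. Fatty acid and triglyceride synthesis rose by 0.29 ± 0.38 (13 of 17 higher, adjusted p = 0.0117, adjusted p = 0.983 with an estimated correlation), with Acss2 at 0.60 ± 0.36. The T cell and erythroid adjusted p values were 0.0522 and 0.118 with slide as a fixed block. The T cell call ended without control replicate 2 or 3 or BPA250 replicate 4 or 5 (-0.59 to -0.33), the erythroid call without control replicate 2, 3 or 5 or BPA250 replicate 2, 3 or 4 (-0.54 to -0.31), and the fatty acid call without control replicate 1 or 2 or BPA250 replicate 5 (0.11 to 0.18), while it was 0.44 without control replicate 3 and 0.45 without BPA250 replicate 2. These 4 lists had 0 members passing when adjusted over the list alone.

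Limma called 0 of 16157 genes between BPA250 and control (160 at an unadjusted p under 0.05). The leading lower values were muscle genes: Tnni1, Ppp1r27 (-2.48 ± 0.81), Myog (the myogenic factor myogenin, -2.50 ± 0.86), Csrp3 (muscle LIM protein, -2.56 ± 0.89) and Atp1b4 (-2.75 ± 0.96). The leading higher values were Tnfsf13b (the B cell survival factor BAFF, 1.12 ± 0.34), Tssk1b (1.73 ± 0.61), Arhgef17 (1.41 ± 0.54), Cby2 (1.44 ± 0.58) and Fbxl7 (1.11 ± 0.45). All had an adjusted p of 1 in limma. Arhgef17 was higher on 1 of 3 shared slides, and Tnni1 and Csrp3 were lower on 2 of 3. Cby2 was above background on 2 of 5 BPA250 and 1 of 5 control arrays, and Arhgef17 on 4 and 2. The 5 muscle genes were above background on 2 of 5 BPA250 arrays each. The sizes of these differences are therefore uncertain.

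The BPA doses differed from each other in muscle transcripts by -2.63 ± 1.20 (BPA250 minus BPA25, camera adjusted p = 2.9e-35), a call that missed the threshold with an estimated correlation (adjusted p = 0.0758). Cholesterol synthesis differed by -0.31 ± 0.25 (adjusted p = 0.00185, adjusted p = 0.867 with an estimated correlation) and fatty acid synthesis by -0.43 ± 0.38 (adjusted p = 0.00304, adjusted p = 0.867 with an estimated correlation). These are 3 of 10 lists that passed at the preset correlation, and none of the 10 passed with an estimated correlation. These dose differences of lists were tested after the single comparisons had been seen. Limma called 0 genes between the doses (272 at an unadjusted p under 0.05) and 0 for the mean of both doses against control (151 at an unadjusted p under 0.05).

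When genistein was added to BPA25, skeletal muscle transcripts fell by 3.77 ± 1.20 relative to all genes, with 23 of 23 lower. Tnnt1 (slow troponin T) stood at -3.20 ± 0.76, Myh7 at -4.66 ± 1.22, Tnni1 at -3.14 ± 0.83 and Myh2 (fast myosin) at -6.04 ± 1.65 (its other probe at -3.71). When adjusted over the list alone 22 of the 23 passed, and 0 passed over all genes. Camera gave an adjusted p of 1.1e-37, with an adjusted p of 0.0571 with an estimated correlation. The list mean was -1.27 (SD 2.55) against 2.49 (SD 0.99), with an exact permutation p of 0.0397 (5 against 5 arrays, adjusted 0.727). Of the 2 slides with both groups, slide 7 had the genistein array lower (-4.5) and slide 3 had it higher by 2.32. The shift was -2.51 ± 1.27 with slide as a fixed block and -5.29 ± 1.19 without slide 3.

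Cholesterol synthesis fell by 0.56 ± 0.25 with genistein at this dose, with 15 of 16 members lower, and fatty acid and triglyceride synthesis by 0.72 ± 0.38, with 14 of 17 lower. Fdps stood at -1.07 ± 0.42, Sc5d (lathosterol oxidase) at -0.71 ± 0.32, Lss (lanosterol synthase) at -0.81 ± 0.38 and Scd2 (stearoyl-CoA desaturase) at -2.47 ± 0.94. The brightest probe stands for each gene: the 3 Scd2 probes ran from -2.47 to -0.81 and the 2 Fdps probes from -2.07 to -1.07. Camera adjusted p values were 7.6e-06 and 7.2e-05, and with an estimated correlation the adjusted p values were 0.563 and 0.716. The exact permutation p was 0.0714 and 0.167 (5 against 5 arrays). Both lists were lower on 2 of 2 shared slides. The fatty acid call ended without BPA25+genistein replicate 2 (-0.40). Both lists had 0 members passing when adjusted over the list alone.

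**Figure D3:**
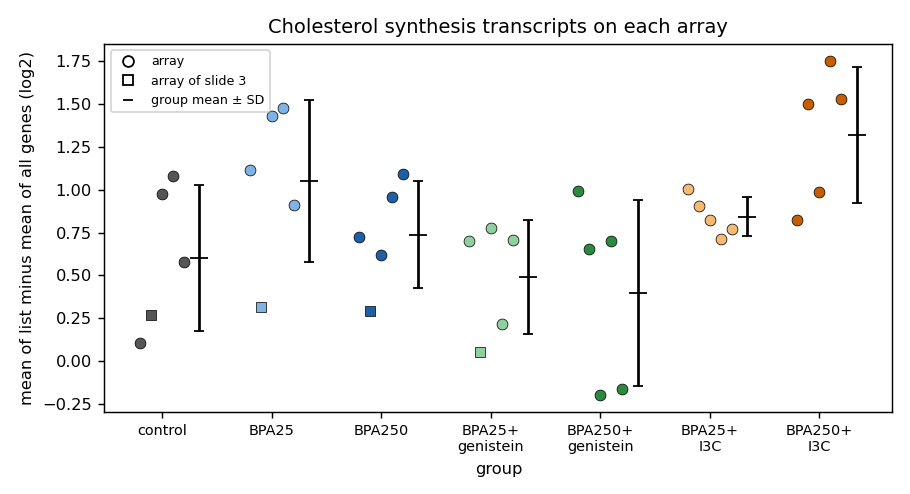
Mean of the cholesterol synthesis list minus the mean of all genes (log2, y axis) on each array by group (x axis), with squares for the arrays of slide 3 and a bar for the group mean and SD (n = 5). The group mean was 0.60 in control, 1.05 with BPA25, 0.49 with BPA25+genistein and 1.32 with BPA250+I3C, and the spread within groups (SD up to 0.54) is as wide as most of these differences.

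Cell cycle transcripts fell by 0.37 ± 0.25 with genistein added to BPA25 (25 of 26 lower, camera adjusted p = 0.000411, adjusted p = 0.683 with an estimated correlation), with Cdc20 at -0.77 ± 0.38. Schwann cell markers fell by 0.72 ± 0.27 (7 of 8 lower, adjusted p = 0.00161, adjusted p = 0.322 with an estimated correlation), with Prx (-1.54 ± 0.48) among the members that passed when adjusted over the list alone. Endothelial markers fell by 0.31 ± 0.16 (9 of 13 lower, adjusted p = 0.0257, adjusted p = 0.471 with an estimated correlation), with Eng at -1.19 ± 0.45. The endothelial adjusted p was 0.0517 with slide as a fixed block, and the call ended without BPA25 replicate 1 or 2 or BPA25+genistein replicate 1 or 4 (-0.30 to -0.21). The cell cycle shift was -0.56 ± 0.29 with slide as a fixed block, and the Schwann call ended without the arrays of slide 3 (-0.72).

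A single gene passed over all 16157 genes, Myoz2 (calsarcin-1, a slow-muscle protein, on chromosome 2 from 213826052 to 213852778 of GRCr8). It fell by 3.90 ± 0.67 on the log2 scale (limma adjusted p = 0.0321), from -0.74 (SD 0.70, n = 5) to -4.63 (SD 0.98, n = 4). None of these 4 genistein values was above background, so Myoz2 was at least 3.95-fold lower. In all, 764 genes, Myoz2 included, had an unadjusted p under 0.05, where chance alone gives 808. The missing genistein value is an outlier-flagged spot on slide 3 that read 0.41, and with outlier spots kept the call was lost (0 genes). The next lower values were Tceal7 (-3.76 ± 0.88), Tnnt1, Myh6 (alpha myosin, -4.46 ± 1.10) and Myh7, all with an adjusted p of 0.877 in limma. The leading higher values were Cdk12 (1.26 ± 0.33), Mrgprb2 (a mast cell receptor, 2.07 ± 0.56), Nhsl1 (1.28 ± 0.38), Lat2 (an adaptor of B and mast cells, 1.54 ± 0.49) and Cntrl (centriolin, 1.25 ± 0.42), with adjusted p values of 0.877 to 0.92. Mrgprb2, Nhsl1 and Lat2 were each above background on 1 of 5 BPA25 arrays, so the sizes of their differences are uncertain. Leaving out BPA25+genistein replicate 2, the slide 3 array, gave 7 genes with Myh6, Myh7, Myoz2, Tceal7 and Tnni1 among them, while leaving out BPA25 replicate 1, 2, 4 or 5 or BPA25+genistein replicate 1, 3 or 5 gave 0.

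When genistein was added to BPA250, T cell markers rose by 1.24 ± 0.79 relative to all genes, with 7 of 7 higher (Cd3e 1.85 ± 0.86, Cd3d 1.52 ± 0.81, Zap70 1.41 ± 0.78). Cell cycle transcripts fell by 0.43 ± 0.25 (24 of 26 lower, Mcm6 -0.71 ± 0.38), cholesterol synthesis by 0.34 ± 0.25 (12 of 16 lower, Sc5d -0.68 ± 0.32, Sqle -0.79 ± 0.40) and muscle by 1.13 ± 1.20 (21 of 23 lower, Acta1 -2.84 ± 1.51). Schwann cell markers rose by 0.47 ± 0.27 (6 of 8 higher), with Prx (1.58 ± 0.48) and Mbp (1.56 ± 0.55) passing when adjusted over the list alone. The other 4 lists had 0 such members. In the order T cell, cell cycle, cholesterol, muscle and Schwann, the camera adjusted p values were 0.000556, 4.9e-05, 0.00601, 0.000196 and 0.0257, and the adjusted p values with an estimated correlation were 0.619, 0.602, 0.878, 0.878 and 0.563. The exact permutation p of the T cell list was 0.0397 (5 against 5 arrays, adjusted 0.727), and it was higher on 2 of 2 shared slides. The genistein array was lower on both shared slides for cell cycle (-0.72 and -0.60) and cholesterol synthesis (-1.25 and -0.81), and Schwann cell markers went both ways (-0.44 and 0.70). In same-number pairs the T cell list was higher in 4 of 5, Schwann in 4 of 5, and cell cycle, muscle and cholesterol synthesis lower in 4, 4 and 3 of 5 (exact sign-flip permutation p = 0.125, 0.312, 0.25, 0.125 and 0.438, adjusted 0.768 each).

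The cholesterol shift at this dose was, with slide as a fixed block, -0.69 ± 0.21, while the muscle shift was -0.50 ± 1.22 (adjusted p = 0.845; -2.97 and -1.78 on the 2 shared slides) and the Schwann call was lost (0.42 ± 0.30, adjusted p = 0.203). Single arrays decided several of these calls. Cholesterol was lost without BPA250+genistein replicate 3 or 5 (-0.20 to -0.19), muscle without BPA250 replicate 2 or BPA250+genistein replicate 5 (-0.66 to -0.61), and Schwann without BPA250 replicate 1, 4 or 5 or BPA250+genistein replicate 1 or 2 (0.29 to 0.47). Without BPA250 replicate 1 the cell cycle shift was -0.70, and without BPA250 replicate 4 the muscle shift was -1.87. Limma called 0 of 16157 genes (680 at an unadjusted p under 0.05). The leading higher values were Tp53inp1 (a p53-induced gene, 1.03 ± 0.29), Tox (a T cell transcription factor, 0.85 ± 0.25), Slc16a11 (1.07 ± 0.31), Prx and Apod (apolipoprotein D, 1.44 ± 0.44). The leading lower values were Dcx (doublecortin, -1.66 ± 0.38), Hspbp1 (an Hsp70 cochaperone, -0.93 ± 0.25), Rbl1 (the pocket protein p107), B4galt2 (-1.19 ± 0.32) and Grwd1 (-1.04 ± 0.28). Rbl1 stood at -1.43 ± 0.38 but was above background on 0 of 5 genistein arrays, and turned to 0.07 with normexp correction. Their adjusted p values were 0.811 to 0.957 in limma. With slide as a random block, as planned, limma called 76 genes (40 higher, 36 lower), with Tp53inp1, Tox, Slc16a11, Dcx, Hspbp1, Rbl1, B4galt2 and Grwd1 among them (adjusted p = 0.0339 to 0.0361), and with slide as a fixed block it called 4. Of the 76 genes, 36 were called again with the random block when slide 3 was left out.

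Averaged over both BPA doses, genistein went with cholesterol synthesis transcripts lower by 0.45 ± 0.18 (-0.45) relative to all genes, with 15 of 16 members lower. With the arrays of both doses averaged on each slide, the list mean was lower on 4 of 4 slides that held arrays with and without genistein. It was also lower on each slide when arrays of the same dose were compared. With slide as a fixed block the shift was -0.65 ± 0.16. This average of lists was tested after the single comparisons had been seen. Its exact permutation p, with labels exchanged within each dose, was 0.0294 (adjusted 0.274, 10 against 10 arrays), the camera adjusted p 6.2e-06 and the adjusted p 0.402 with an estimated correlation. Fatty acid and triglyceride synthesis stood at -0.44 ± 0.27, and at -0.80 ± 0.22 with slide as a fixed block. Its exact permutation p was 0.164 (adjusted 0.578), and its camera adjusted p 0.947 with an estimated correlation.

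Limma called 0 genes for this average (1481 at an unadjusted p under 0.05, where chance alone gives 808 on average). This is no evidence of an excess over chance, since another grouping of the same arrays called 5960 genes even after adjustment. With slide as a random block, as planned, it called 390, of which 206 were higher and 184 lower. All 390 had the same direction without a block and with slide as a fixed block, where 0 passed. Since these fits use the same arrays, the shared direction is no independent evidence for the calls. Among the 134 lower genes with a symbol were Sqle (-0.98 ± 0.24), Sc5d (-0.88 ± 0.21), Fdps (-0.86 ± 0.23), Nsdhl (-0.84 ± 0.23) and Fdft1 (-0.83 ± 0.21), all enzymes of sterol synthesis, together with Scd2 (-2.21 ± 0.57), Pnpla3 (-1.47 ± 0.40), Gpd1 (glycerol phosphate synthesis, -1.09 ± 0.26), Slc3a2 (an amino acid transporter chain, -1.49 ± 0.37), Ltbr (lymphotoxin beta receptor, -1.48 ± 0.36), Mfap2 (a microfibril protein, -1.49 ± 0.38) and Myoz2 (-2.06 ± 0.41). Among the 58 higher ones were Cyp2e1 (a cytochrome P450, 1.91 ± 0.47), Mylip (the ubiquitin ligase of the LDL receptor, 1.53 ± 0.31), Bola1 (1.44 ± 0.37) and Mrgprb2 (1.38 ± 0.37). Adjusted p values of these genes in limma with the block were 0.0211 to 0.0457. For Myoz2 the outlier-flagged spot of BPA25+genistein replicate 2, which read 0.41, was filled with its group's mean, so its spread is understated.

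When I3C was added to BPA25, muscle and proliferation transcripts were both lower. Skeletal muscle markers fell by 3.46 ± 1.20 relative to all genes, with 23 of 23 lower, 23 of them passing when adjusted over the list alone and 1 over all genes. Cell cycle transcripts fell by 0.85 ± 0.25, with 26 of 26 lower: Cenpf (kinetochore, -1.18 ± 0.39, its other probe -0.55), Ccnb1 (cyclin B1, -1.04 ± 0.36), Kif20a (a mitotic kinesin, -0.89 ± 0.33) and Ccnb2 (cyclin B2, -1.20 ± 0.46), with 0 members passing when adjusted over the list alone. Camera adjusted p values were 1.2e-43 and 1.6e-21, and both calls held with an estimated correlation (adjusted p = 0.0441 each). Exact permutation p values of the list means were 0.0476 and 0.0238 (5 against 5 arrays, adjusted 0.727 each). Slide 9 alone held both groups. There the I3C array, BPA25+I3C replicate 4, had muscle transcripts higher by 0.37 and cell cycle transcripts lower by 1.46 (-1.46). The shifts were -2.26 ± 1.33 and -0.94 ± 0.30 with slide as a fixed block.

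Markers of the epithelium moved with them. Luminal epithelium markers fell by 0.96 ± 0.45 (9 of 12 lower, adjusted p = 9.0e-06, adjusted p = 0.322 with an estimated correlation), with the luminal keratins Krt18 (-2.37 ± 1.02, its other probe -1.56) and Krt19 (-1.34 ± 0.54) and the adherens junction gene Cdh1 (-1.63 ± 0.74). Basal and myoepithelial markers fell by 0.63 ± 0.34 (7 of 8 lower, adjusted p = 0.00112, adjusted p = 0.322 with an estimated correlation), with Jag2, a Notch ligand, at -0.82 ± 0.35. Milk protein and secretory genes fell by 0.66 ± 0.38 (6 of 10 lower, adjusted p = 0.023, adjusted p = 0.471 with an estimated correlation). Their median member moved by -0.06. When adjusted over the list alone Csn3 (kappa casein) and Lalba (alpha lactalbumin, -2.77 ± 0.89) passed, and Csn3, above background on 0 of 5 I3C arrays, was at least 1.63-fold lower. Without BPA25+I3C replicate 4 the luminal shift was -0.54 and the basal call was lost (-0.36). The basal call was also lost with slide as a fixed block (-0.40 ± 0.38, adjusted p = 0.203), the milk call too (-0.64 ± 0.50, adjusted p = 0.236). The milk call ended without BPA25 replicate 2 or 5 or BPA25+I3C replicate 2 or 4 (-0.59 to -0.36), and without BPA25 replicate 4 the milk and basal shifts were -0.99 and -0.95. Leaving out the slide 3 arrays ended the luminal, basal and milk calls (-0.74, -0.57 and -0.59).

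Schwann cell markers fell by 0.68 ± 0.27 with I3C (7 of 8 lower, adjusted p = 0.000725, adjusted p = 0.322 with an estimated correlation), with Mbp at -1.13 ± 0.55. T cell markers fell by 0.71 ± 0.79 (7 of 7 lower, adjusted p = 0.0123, adjusted p = 0.825 with an estimated correlation), with Cd3e at -1.07 ± 0.86. Fatty acid and triglyceride synthesis fell by 0.40 ± 0.38 (13 of 17 lower, adjusted p = 0.0162, adjusted p = 0.983 with an estimated correlation), with Acss2 at -0.96 ± 0.36. The luminal, basal and these 3 lists had 0 members passing when adjusted over the list alone. Blocking by slide, the T cell shift was -0.12 ± 0.98 (adjusted p = 0.845) and the fatty acid shift -0.86 ± 0.32. The T cell call ended without BPA25 replicate 2, 3 or 5 or BPA25+I3C replicate 4 (-0.64 to -0.24) and was -1.27 and -1.15 without BPA25 replicates 1 and 4. The fatty acid call ended without BPA25 replicate 3 or 4 (-0.28 to -0.21) and was -0.67 without BPA25 replicate 2.

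Gene by gene, 2 muscle genes passed with I3C added to BPA25. Tnni1 (chromosome 13, 49781529 to 49793385 of GRCr8) fell by 4.62 ± 0.83 on the log2 scale (limma adjusted p = 0.0335), from 0.93 (SD 1.13, n = 5) to -3.69 (SD 1.06, n = 5). It was above background on 0 of 5 I3C arrays, so it was at least 11.9-fold lower. Myoz2 fell by 3.51 ± 0.64 (limma adjusted p = 0.0335), from -0.74 (SD 0.70, n = 5) to -4.25 (SD 1.13, n = 5), but was above background on 1 of 5 I3C arrays, so the size of its difference is uncertain. On slide 9 both were lower, with I3C values not above background. In all, 699 genes, these 2 included, had an unadjusted p under 0.05, where chance gives 808. Ankrd2 (-2.84 ± 0.66), Tnnt1 (-3.26 ± 0.76) and Myh6 (-4.63 ± 1.10) came next, with adjusted p values of 0.294 to 0.328, and the leading higher values were Cdk12 (1.30 ± 0.33), Dlc1 (a tumour suppressor gene, 0.96 ± 0.26), Cited2 (a transcriptional coregulator, 1.17 ± 0.35), Scgb3a1 (a secretoglobin, 1.84 ± 0.56) and Ank2 (0.92 ± 0.31, its other probe 0.23), with adjusted p values of 0.473 to 0.936. Within the remaining lists Igfbp2 and Areg (an oestrogen-responsive EGF receptor ligand), above background on 0 of 5 I3C arrays, were at least 1.25-fold and 1.90-fold lower and Tff1 higher (1.18 ± 0.41), all 3 passing when adjusted over the list alone and none over all genes. With slide as a fixed block, with outlier spots kept or with normexp correction 0 genes were called. Leaving out BPA25+I3C replicate 4 gave 22 genes, leaving out BPA25 replicate 2 gave 1 (Tnni1), and leaving out BPA25 replicate 1, 3, 4 or 5 or BPA25+I3C replicate 1, 3 or 5 gave 0.

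When I3C was added to BPA250, erythroid markers rose by 1.40 ± 0.41 relative to all genes, with 6 of 6 higher. Slc4a1 (the red cell anion exchanger, 1.99 ± 0.47), Alas2 (erythroid haem synthesis, 2.37 ± 0.62) and Hbb (beta globin, 1.45 ± 0.62) were among the members that passed when adjusted over the list alone, and 0 passed over all genes. Camera gave an adjusted p of 9.0e-06, with an adjusted p of 0.322 with an estimated correlation. The exact permutation p of the list means was 0.0476 (3.76, SD 1.24, against 2.37, SD 0.53, 5 against 5 arrays, adjusted 0.727). The shift was 1.46 ± 0.40 with slide as a fixed block and 1.67 on slide 1, the 1 slide with both groups.

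Cholesterol synthesis rose by 0.58 ± 0.25 with I3C at this dose (15 of 16 higher, adjusted p = 9.7e-05, adjusted p = 0.676 with an estimated correlation), with Fdps (1.38 ± 0.42) passing when adjusted over the list alone, followed by Cyp51 (0.84 ± 0.32) and Sqle (0.96 ± 0.40). The shift was 0.25 ± 0.22 with slide as a fixed block (adjusted p = 0.0528). Oxidative phosphorylation rose by 0.52 ± 0.32 (19 of 19 higher, adjusted p = 0.000919, adjusted p = 0.983 with an estimated correlation), with Cox5b at 0.94 ± 0.51, and stood at 0.04 with quantile normalisation, 0.17 ± 0.15 with slide as a fixed block and 0.26 without BPA250 replicate 2. Muscle transcripts fell by 2.03 ± 1.20 (23 of 23 lower, adjusted p = 1.0e-14, adjusted p = 0.471 with an estimated correlation), with Ckm (muscle creatine kinase) at -3.95 ± 1.84. On slide 1 the differences were -0.11 for muscle, 0.10 for cholesterol synthesis, 0.40 for oxidative phosphorylation, -0.15 for luminal and 0.06 for Schwann cell markers. Luminal epithelium markers fell by 0.66 ± 0.45 (11 of 12 lower, adjusted p = 0.00054, adjusted p = 0.471 with an estimated correlation), with Krt8 at -1.27 ± 0.62 (4 BPA250 arrays). Schwann cell markers fell by 0.52 ± 0.27 (7 of 8 lower, adjusted p = 0.0109, adjusted p = 0.471 with an estimated correlation), with Gldn at -0.69 ± 0.45, a call that ended without BPA250 replicate 3 (-0.35). Oxidative phosphorylation, muscle, luminal and Schwann lists had 0 members passing when adjusted over the list alone.

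Limma called 0 of 16157 genes for I3C added to BPA250 (699 at an unadjusted p under 0.05). The leading higher values were Npy (neuropeptide Y, 2.05 ± 0.43), Slc4a1, Rsad2 (viperin, an interferon-induced antiviral gene, 1.97 ± 0.49), Alas2 and Exosc2 (2.70 ± 0.72). The leading lower values were B3galt1 (-1.51 ± 0.42), Nhsl1 (-1.34 ± 0.38), Hpd (tyrosine catabolism, -1.53 ± 0.45), Casq2 (a muscle calcium-binding protein, -1.82 ± 0.54) and Card10 (-1.08 ± 0.32), with adjusted p values of 0.606 to 0.766 in limma. In lists that did not pass, Rsad2 and Ifit1 (1.72 ± 0.50) among 11 interferon-stimulated genes, Ucp1 (the uncoupling protein of brown fat, 2.89 ± 0.84) and Cpt1b (1.27 ± 0.48) among 7 brown adipocyte markers, and Csn3 (-1.69 ± 0.55) among 10 milk genes passed when adjusted over the list alone and 0 over all genes. With slide as a random block limma called 2 genes, Alas2 (2.44 ± 0.42, adjusted p = 0.022) and Npy (2.22 ± 0.39, adjusted p = 0.022). Averaged over both BPA doses it called 0 genes for I3C (866 at an unadjusted p under 0.05), and with slide as a random block Myoz2 (-2.33 ± 0.43) and Npy (1.63 ± 0.30), each with an adjusted p of 0.0404. None of these random-block calls, at BPA250 or over both doses, was made again without slide 3.

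The effect of a diet was compared between BPA doses. The Schwann cell list differed in its response to genistein, with a difference of 1.19 ± 0.39 (the shift at BPA250 minus that at BPA25, camera adjusted p = 5.0e-08), a call that held with an estimated correlation (adjusted p = 0.0396). Part of it lies between the groups without genistein (-0.54 ± 0.27, BPA250 minus BPA25). I3C responses differed for cell cycle by 0.89 ± 0.36 (adjusted p = 4.6e-14, adjusted p = 0.137 with an estimated correlation) and for cholesterol synthesis by 0.79 ± 0.35 (adjusted p = 1.6e-06, adjusted p = 0.588 with an estimated correlation). Of the lists tested, 6 passed for genistein and 8 for I3C at the preset correlation, and of these 14 only the Schwann list with genistein passed with an estimated correlation. For erythroid markers the difference was 1.07 ± 0.59 (adjusted p = 0.00304, adjusted p = 0.664 with an estimated correlation). Limma called 0 genes for either difference (187 for genistein and 511 for I3C at an unadjusted p under 0.05), and with slide as a random block 0 and 8. Lists were compared between doses after the single comparisons had been seen.

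**Figure D4:**
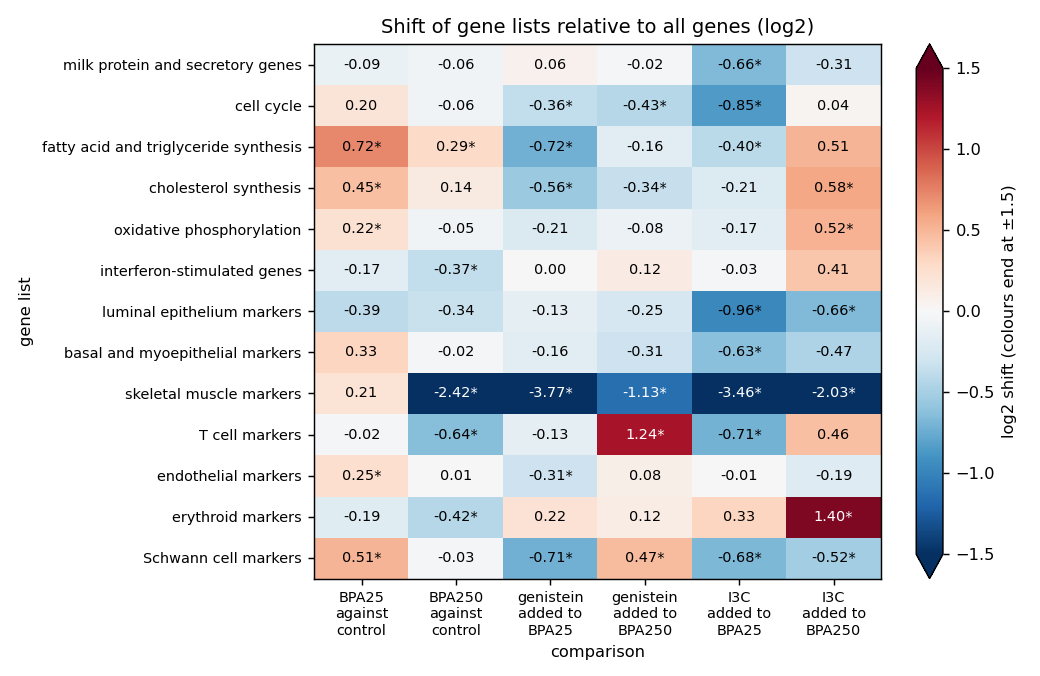
Shift of each gene list called at least once (y axis) in the 6 comparisons (x axis), as the mean log2 fold change of its members minus that of all genes, with an asterisk where limma's camera passed at the preset correlation. Muscle stands at -3.77 and -3.46 for genistein and I3C added to BPA25, and 3 of the 35 asterisks hold with an estimated correlation.

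The combined groups were also set against control. Limma called 0 genes for BPA25+genistein (271 at an unadjusted p under 0.05), 0 for BPA250+genistein (689), 0 for BPA25+I3C (253) and 0 for BPA250+I3C (586). With slide as a random block BPA25+genistein gave Myoz2 (-3.19 ± 0.55, adjusted p = 0.0232). There the outlier-flagged Myoz2 spot of BPA25+genistein replicate 2, which read 0.41, was filled with the mean of its group. This fill narrows the spread, and Myoz2 was not called again without slide 3. BPA250+genistein gave 3 genes with Ifi47, an interferon-induced GTPase, among them (-1.09 ± 0.20, adjusted p = 0.0275). BPA250+I3C gave 87 genes with this block (30 of them called again without slide 3), 67 lower and 20 higher. The lower ones held 15 of the 23 measured members of the skeletal muscle list, such as Ckm (-7.11 ± 1.59), Tnnc2 (-6.90 ± 1.63), Myh4 (-6.74 ± 1.53) and Acta1 (-6.00 ± 1.31), and Alas2 (1.96 ± 0.40), Slc4a1 (1.85 ± 0.41), Npy (1.81 ± 0.37) and Fdps (1.38 ± 0.30) were among the higher. The F test over all 7 groups called 1 gene, Myoz2 (limma adjusted p = 0.0467), with 652 at an unadjusted p under 0.05.

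Other lists were not called in any of the 6 comparisons. Oestrogen-responsive genes (11 measured) had shifts of -0.15 to 0.18 and a smallest camera adjusted p of 0.316, nuclear and hormone receptors (9) -0.15 to 0.05 and 0.573, Nrf2 targets (8) -0.11 to 0.23 and 0.277, the Wnt pathway (18) -0.27 to 0.15 and 0.0519, and growth factors and their receptors (16) -0.15 to 0.12 and 0.299. Apoptosis (16) ran from -0.15 to 0.15 (smallest 0.259), DNA repair (15) from -0.20 to 0.08 (0.207), DNA methylation and chromatin (11) from -0.11 to 0.26 (0.116), immediate early genes (12) from -0.15 to 0.15 (0.402), heat shock and unfolded protein response (12) from -0.27 to 0.28 (0.0848) and extracellular matrix (22) from -0.26 to 0.12 (0.0645). Among cell types, white adipocyte markers (15) ran from -0.31 to 0.25 (0.0645), brown adipocyte markers (7) from -0.60 to 0.23 (0.232), macrophage markers (14) from -0.17 to 0.17 (0.195) and mast cell markers (7) from -0.24 to 0.25 (0.166). A further 3 lists had too few measured members to test: aryl hydrocarbon receptor targets (4, from Cyp1b1 to Ugt1a6, the largest value 0.54 ± 0.29 for Ugt1a6 with genistein added to BPA25), B cell markers (3, the largest 1.54 ± 1.19 for Cd79b with genistein added to BPA250) and epidermal keratinocyte markers (2, the largest -0.86 ± 0.57 for Krt1 with I3C added to BPA250). None of their members passed. Besides the members named with I3C above, 0 members of these lists passed when adjusted over the list alone.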

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

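The tests of slide 3, of slides behind the muscle and sterol patterns, of shared BPA25 arrays and of the dietary compounds were chosen after the results were seen, and the test of muscle tissue amounts and the regroupings of arrays were set beforehand.

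In 11 of 112 sets of 5 arrays, 1 array lay far from the other 4, where chance alone gives about 1 in 20, and 7 of the 11 were on slide 3. The percent of probes well above background was 93.4 on control replicate 2 (others 41.1 to 47.9), 94.7 on BPA25 replicate 2 (others 39.1 to 49.8) and 68.6 on BPA25+I3C replicate 2 of slide 4 (others 41.5 to 48.2). Oxidative phosphorylation genes had a list mean of 3.29 on BPA25 replicate 2 (others 4.40 to 4.65) and of 2.87 on BPA25+genistein replicate 2 (others 4.15 to 4.64). Erythroid markers stood at 1.77 on BPA25+genistein replicate 2 (others 2.92 to 3.21). Skeletal muscle markers stood at 0.78 on BPA25 replicate 2 (others 2.51 to 3.16) and at 3.1 on BPA25+genistein replicate 2 (others -3.27 to -1.54). Away from slide 3, cell cycle genes stood at -0.03 on BPA250+I3C replicate 4 (others -0.77 to -0.59), basal and myoepithelial markers at -1.28 on BPA25+genistein replicate 1 (others -0.44 to -0.16), and Myoz2 at -2.28 on BPA25+I3C replicate 2 (others -5.05 to -4.40).

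Schwann cell markers moved apart between BPA doses when genistein was added, with a difference of 1.19 ± 0.39 between the shift at BPA250 (0.47) and that at BPA25 (-0.72), tested with limma's camera (adjusted p = 5.0e-08, adjusted p = 0.0396 with an estimated correlation). Prx and Mbp, both myelin genes, led it at BPA250 (1.58 ± 0.48 and 1.56 ± 0.55), and Prx was lower at BPA25 (-1.54 ± 0.48). Prx was above background on 2 of 5 arrays with BPA250 alone, and at that dose it was higher on 1 of 2 shared slides. No technical or biological explanation of this difference was tested.

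Skeletal muscle transcripts were lower when genistein (-3.77 ± 1.20) or I3C (-3.46 ± 1.20) was added to BPA25. No table excludes an explanation here. Muscle tissue carried along in the dissected gland, in amounts that differ between animals, may be a source. Of the variance of the 23 members within groups, 82.4% lies in 1 component. Any joint change of these genes would give such a component, so this value does not favour tissue amount over the other explanations. Differences between slides stay open, since with slide as a fixed block the smaller of both shifts was -2.26 ± 1.33. An effect of the diets stays open too. Its exact permutation p was 0.727 after adjustment (5 against 5 arrays). This test cannot decide, since its smallest p is 0.00794 and the adjustment ran over 168 pairs. How much muscle was dissected with each gland cannot be told apart from a dietary effect on the animals.

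Sterol and fatty acid synthesis transcripts were higher with BPA25 than in control and lower when genistein was added. None of these list calls passed with an estimated correlation or by the exact permutation after adjustment, so chance stays open. Were the sterol shift more than chance, slide differences would hardly be its whole cause. The list stood at 0.47 ± 0.20 with slide as a fixed block for BPA25 against control. For the sterol list, the values argue against the BPA25 arrays shared by both comparisons as the whole cause of the genistein part. Genistein added to BPA250, fitted without the BPA25 arrays, gave -0.72 ± 0.21 with slide as a fixed block. Without the block the sterol shift was -0.34 ± 0.25, and 3 of 5 same-number pairs were lower. The camera call without the block was lost when BPA250+genistein replicate 3 or 5 was left out (list means -0.195 and -0.158). The fatty acid list was not fitted without the BPA25 arrays. For genistein added to BPA250 its mean difference over same-number pairs was -0.157. White adipocyte markers, a measure of fat, stood at 0.15 ± 0.13, -0.32 ± 0.14 and -0.05 ± 0.14 with slide as a fixed block (BPA25 against control, then genistein added to BPA25 and to BPA250), and the amount of fat or epithelium and an effect of BPA or genistein stay open.

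With slide as a random block limma called 390 genes for genistein over both BPA doses, and 0 without the block (1481 at an unadjusted p under 0.05). The 4 arrays of slide 3 are argued against as the source of most of these calls, since 318 of the 390, with Sqle, Sc5d, Fdps, Nsdhl and Fdft1 among them, were called without slide 3 too. The cholesterol list had 5 members called with this block and 6 without slide 3, but the fatty acid list had 2 and 0. By this count alone chance can be excluded, with 390 genes in the real grouping and at most 295 in the other splits (1 of 100 splits as large). But the splits moved arrays across slides, another split still called 295 genes, and slide as a fixed block left 0. The exclusion of chance is therefore not firm. An effect of genistein and differences between animals or litters stay open.

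Other groupings of the same arrays, 100 per comparison with the real one included, were fitted in the same way. By this count alone chance can be excluded for I3C added to BPA25 (2 genes, highest other 111, 3 of 100 splits as large) and for the F test over the 7 groups (1 gene, highest other 4260, 3 of 100). These were 2 of 17 comparisons counted in this way, the splits moved arrays across slides, and blocking by slide left 0 genes for I3C added to BPA25, so neither is firm. Chance cannot be excluded for genistein added to BPA25 (1 gene, highest other 51, 6 of 100) or for the 35 called pairs of list and comparison (highest other 52, 14 of 100, other splits 8 to 52 with a median of 27). The remaining comparisons gave 0 genes in limma, so all 100 splits were as large. Their highest other counts were 1 for BPA25 against control, 0 for BPA250 against control, 1 for BPA250 against BPA25, 9637 for both BPA doses against control, 1 for genistein added to BPA250, 5960 for genistein over both doses, 0 for I3C added to BPA250, 1 for I3C over both doses, 0, 1, 58 and 0 for BPA25+genistein, BPA250+genistein, BPA25+I3C and BPA250+I3C against control, and 5 and 2 for the dose differences of genistein and I3C. Their counts at an unadjusted p under 0.05 were 324, 160, 272, 151, 680, 1481, 699, 866, 271, 689, 253, 586, 187 and 511 in the same order.

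The 3 splits with the most genes placed slide 3 arrays together, which points to a structure of the arrays. In the split with 9637 genes 3 slide 3 arrays were in the control group, in the split with 5960 genes 3 were in the BPA250 group, and in the split with 4260 genes 2 each were in the BPA250 and BPA250+genistein groups. The split with 51 genes had 2 in the genistein group, and the arrays behind the splits with 111 and 58 genes include a single slide 3 array each. Blocking by slide as a fixed term, limma called 0 genes for genistein added to BPA25, for I3C added to BPA25 and for genistein over both doses. Same-number arrays correlated above 0.1 in all 5 pairs for BPA25 against control and genistein added to BPA250, though the labels state no pairing. Among splits that part all 5 pairs, 10 and 11 others gave at most 0 genes, as did the real ones.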

How the results depend on the processing

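Leaving out the 4 arrays of slide 3 (with or without slide as a random block), the percentile over detected probes and quantile normalisation with slide as a fixed block were chosen after seeing the data, the other alternatives beforehand. The cause was not tested for any change below, except that unadjusted counts rise by construction. Counts are genes in limma.

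At an unadjusted p under 0.05 the counts were 324 for BPA25 against control, 160 for BPA250 against control, 272 for BPA250 against BPA25, 151 for both doses against control, 764 and 680 for genistein added to BPA25 and BPA250, 1481 for genistein over both doses, 699 and 699 for I3C added to BPA25 and BPA250, 866 for I3C over both doses, 271, 689, 253 and 586 for BPA25+genistein, BPA250+genistein, BPA25+I3C and BPA250+I3C against control, 187 and 511 for the dose differences of genistein and I3C, and 652 for any difference among the 7 groups.

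Array weights gave 145 for BPA25 against control, 2 for BPA250 against control, 39 between the doses, 3 for both doses against control, 74 and 225 for genistein added to BPA25 and BPA250, 763 over both doses, 819 for I3C added to BPA25, 8 for I3C over both doses, 63, 195, 67 and 164 for the combined groups against control, 8 and 443 for the dose differences, and 967 for any difference.

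Slide as a random block gave 76 genes for genistein added to BPA250, 390 for genistein over both doses, 2 for I3C added to BPA250, 2 for I3C over both doses, 1, 3 and 87 for BPA25+genistein, BPA250+genistein and BPA250+I3C against control, 8 for the dose difference of I3C and 136 for any difference. I3C added to BPA25 gave 3. Slide as a fixed block gave 0 for genistein added to BPA25 and 0 for I3C added to BPA25, 4 for genistein added to BPA250, 1 for BPA250+genistein against control, 1 for the dose difference of I3C and 5 for any difference. Correlation within slides was 0.584, and 0.309 without slide 3. Scan day as a fixed block gave 2 for genistein added to BPA25, 5 for genistein over both doses, 5 for I3C added to BPA25, 2, 1, 1 and 1 for the combined groups against control and 9 for any difference. Replicate number as a block gave 2 for genistein over both doses, 4 for I3C added to BPA25 and 1 for the dose difference of genistein.

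Without slide 3 there were 4 genes between the doses, 19 for genistein added to BPA25, 67 for genistein over both doses, 9 for I3C added to BPA25, 1 and 2 for BPA250+genistein and BPA25+I3C against control and 25 for any difference. Adding slide as a random block there were 2 for BPA250 against control, 5 between the doses, 24 and 54 for genistein added to BPA25 and BPA250, 638 over both doses, 13 for I3C added to BPA25, 1, 1, 3 and 40 for the combined groups against control, 3 and 19 for the dose differences and 332 for any difference. Genes called with this block on all arrays were often not called again. For genistein it was 1 of 1 at BPA25, 36 of 76 at BPA250 and 318 of 390 over both doses. For I3C it was 3 of 3 at BPA25, 0 of 2 at BPA250, 0 of 2 over both doses and 7 of 8 for the dose difference. Against control it was 0 of 1 for BPA25+genistein, 1 of 3 for BPA250+genistein and 30 of 87 for BPA250+I3C.

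Genistein added to BPA25, I3C added to BPA25 and any difference fell to 0 genes each with normexp correction, with the authors' table, without a filter, with outlier spots kept and with muscle, B cell and luminal covariates. The authors' table gave 1 for genistein added to BPA250 and 1 over both doses. Quantile normalisation gave 3 for genistein over both doses, 1 for I3C added to BPA25 and 2 for any difference. It gave, when slide was a fixed block as well, 1 between the doses, 0 and 14 for genistein added to BPA25 and BPA250, 59 over both doses, 0 for I3C added to BPA25, 1 for BPA250+genistein against control, 1 for the dose difference of I3C and 11 for any difference. The percentile over detected probes gave 0 for genistein added to BPA25, 6 over both doses, 1 for I3C added to BPA25, 1 for the dose difference of genistein and 2 for any difference. Fitting the compared groups alone gave 0 for genistein added to BPA25, 1 for I3C added to BPA25, and 2 and 67 for BPA250+genistein and BPA250+I3C against control. The stricter filter gave 1 for genistein over both doses and 2 for any difference. Median scaling gave 1 for BPA25+genistein against control and 2 for any difference, and every probe tested separately 0 for any difference.

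With 1 array left out, counts ran from 0 to 1 between the doses (highest without BPA25 replicate 2), 0 to 7 for genistein added to BPA25 and 0 to 2 over both doses (both highest without BPA25+genistein replicate 2). They ran from 0 to 22 for I3C added to BPA25, 0 to 17 over both doses, 0 to 25 for BPA25+I3C against control and 0 to 65 for any difference (each highest without BPA25+I3C replicate 4). The 35 called pairs of list and comparison ran from 33 to 41.

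Of those 35 pairs, 3 passed with an estimated correlation and 0 with fry. Direction held in 34 of 35 under normexp correction, the exception being oxidative phosphorylation in BPA25 against control (-0.088). Calls were lost for 3 more under normexp correction, 5 under quantile normalisation, 10 with slide as a fixed block, 6 with scan day, 1 with replicate number, 8 without slide 3 and 5 with the percentile over detected probes.

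Among single genes, apart from fits with 1 array left out, the call was gained in 7 pairs of gene and setting, lost in 10 and the sign turned in 20, and in the other pairs direction and call held. Rbl1 with genistein added to BPA250 was 0.072 with normexp correction. Cyp1b1 turned for BPA25 against control (-0.02 with quantile normalisation, -0.02 with the percentile over detected probes, -0.33 to 0.42 with 1 array left out), genistein added to BPA25 (slide fixed 0.12, replicate number 0.20, without slide 3 0.34, 1 array left out -0.16 to 0.34), I3C added to BPA25 (normexp -0.016, quantile -0.047, detected probes -0.068, 1 array left out -0.16 to 0.44) and I3C added to BPA250 (slide fixed 0.11, without slide 3 0.11, 1 array left out -0.36 to 0.11). Csn2 turned for BPA25 against control (slide fixed -0.18, without slide 3 -0.007, detected probes -0.033, 1 array left out -0.17 to 0.19), BPA250 against control (normexp 0.18, quantile 0.041, without slide 3 0.01, detected probes 0.039, 1 array left out -0.42 to 0.20) and I3C added to BPA250 (normexp -0.016, detected probes -0.17).

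Signal over background limits some of these values: Esr1, Pgr, Ahr and other receptors were too dim to test, and Tnni1, Csn3, Areg and Igfbp2 were above background on no array with I3C added to BPA25, and Myoz2 on 1. Several leading genes that did not pass, such as Zbtb16, Cby2, Mrgprb2, Nhsl1, Lat2 and Prx, were above background on at most 2 of 5 arrays of a compared group.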

Other observations

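The test of sterol synthesis below was chosen after the result was seen.

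Dietary genistein may lower sterol synthesis transcripts in the gland, a hypothesis formed on these arrays. Cholesterol synthesis genes were lower by 0.45 ± 0.18 (-0.45) over both BPA doses, and Sqle, Sc5d, Fdps, Nsdhl and Fdft1 were among the genes called with slide as a random block. The exact permutation p within doses was 0.0294 (10 against 10 arrays) and 0.274 after adjustment, which leaves it open. No group received genistein without BPA, so an effect of genistein alone could not be compared.

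Other averages over both BPA doses were also tested after the single comparisons, with 10 against 10 arrays and an exact permutation within doses. Slide counts here average all arrays of a slide with and without the diet, whatever their BPA dose. Skeletal muscle markers stood at -2.75 ± 0.85 with I3C (exact p = 0.00652, adjusted 0.259, and adjusted p = 0.034 with an estimated correlation in limma's camera). They were lower on 3 of 3 slides, but this did not hold at the same dose. On slide 9 the BPA25+I3C array stood at 3.53 and the BPA25 array at 3.16. On slide 1 the BPA250+I3C array stood at 0.18 and the BPA250 array at 0.29. On slide 10 the I3C array had no partner of the same dose. With genistein muscle markers stood at -2.45 ± 0.85 (exact p = 0.0147, adjusted 0.259, and adjusted p = 0.111 with an estimated correlation). With slide as a fixed block they stood at -1.502 ± 0.92, and 1 of 4 slides was higher (by 1.82). Cell cycle genes stood at -0.40 ± 0.18 with genistein, with 26 of 26 lower (exact p = 0.042, adjusted 0.32, camera adjusted p = 2.9e-06, adjusted p = 0.326 with an estimated correlation). They were lower on 4 of 4 slides, but at the same dose slide 7 went the other way (BPA25+genistein -0.723, BPA25 -0.945). With I3C the cell cycle list stood at -0.405 ± 0.179, with 24 of 26 lower (exact p = 0.103, adjusted 0.524).

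With I3C, erythroid markers stood at 0.86 ± 0.29 (exact permutation p = 0.0231, adjusted 0.259; adjusted p = 0.265 with an estimated correlation in limma's camera), Schwann cell markers at -0.60 ± 0.19 (exact p = 0.0116, adjusted 0.259; adjusted p = 0.0972 with an estimated correlation) and luminal epithelium markers at -0.81 ± 0.32 (exact p = 0.0473, adjusted 0.32; adjusted p = 0.0972 with an estimated correlation). DNA methylation and chromatin genes stood at 0.18 ± 0.09 (exact p = 0.0218, adjusted 0.259; camera adjusted p = 0.181). None of these averages passed the exact test after adjustment.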
